A study of Homo sapiens with 3 samples.

How the data were processed

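Gene expression was measured by RNA sequencing in 3 libraries of 1 group, purified RGCs derived from the iPSC line 201B7 at differentiation day 40. Per the labels' protocols, cells were dissociated and seeded with 10 µM Y-27632, differentiated with small molecules, and captured with beads against Thy1.2. Libraries were made with a kit that reads the 3′ ends of transcripts, so that a transcript gives about the same number of reads whatever its length. The samples' cell type field names the starting stem cells, while the title and the protocols describe the purified RGCs, and the latter were followed. Replicate numbers were taken from the sample titles.

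The deposited table holds raw counts per gene made by the authors. The submitters' processing notes name STAR 2.7.11b, featureCounts 2.0.6 and the genome build GRCh38 (hg38). The annotation release, the strand setting, the treatment of multi-mapping or overlapping reads and any use of molecular identifiers are not given in the sources used here. PCR copies may therefore be among the counts, and all intervals and limits cover counting error only. The strand setting matters for antisense genes, whose reads cannot be told apart with certainty from those of their sense partners. Pairs such as PYURF and PIGY had identical counts in every library, so reads over shared exons were counted for more than 1 gene, and 9362 of 62503 genes share exon sequence with another gene on the same strand. The length column holds the exon length of each gene in the authors' deposited table.

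The table has 62505 gene rows. The rows of TTN and ANK2 are broken over 6 lines in a way that no longer ties values to named columns, and these 2 genes were left out. No column of another sample is named in the header (0 such columns). There are 0 rows for mitochondrially encoded genes and 0 of type rRNA, so shares of these could not be given. Total counts were 10899049, 4456597 and 6023896 in replicates 1, 2 and 3. Genes are named by the table's own symbols, or by Ensembl identifier where 1 symbol stands for several genes. 1 listed gene, TDGF1, was matched through its older symbol to CRIPTO. All coordinates are those of the deposited table.

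Levels were computed as CPM with edgeR 4.0.16 TMM factors of 0.941, 1.01 and 1.05. The level test was edgeR's quasi-likelihood F test of an intercept-only model with an offset set so that the intercept is the log ratio to 10 CPM. edgeR's test function does not take a model of 1 column, so its F statistic was written out from the fitted dispersions and tested on simulated data. Libraries were simulated with the real library sizes, dispersions smoothed over genes of similar level and no TMM step. Differences in spread between genes of the same level were therefore not simulated. With 20795 genes in the fit, 49 of 50 genes at 2-fold above and 49 of 50 at 0.50 times the reference were called in the right direction. All 50 genes at 4-fold above and all 50 at 0.25 times were called, and 5.5% of 200 genes set at exactly 10 CPM were called. Genes with fewer than 10 counts summed over the libraries were not tested, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The p-values measure the spread between these 3 samples, described as independent biological replicates of 1 line. They do not cover other lines.

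Gene lists (22 lists, 319 genes, with 12 of the lists for cell classes that share no gene) and 30 family pairs were fixed before the data were examined. List contrasts compare the median log2(CPM + 1) of the RGC list with that of another list, by a two-sided permutation test of list membership with 100000 resamples. The number of simulated list pairs was raised to 200 after a smaller first run had called more pairs without a difference than the threshold allows. On simulated lists of 22 and 14 genes drawn from 10604 gene values, that test called 4.5% of 200 list pairs with no difference, 45.5% with a shift of 1 log2 unit and 100% with a shift of 3. Those values came from genes of intermediate level only, and fewer resamples were used. The real lists span a wider range (0.0325 to 2591 CPM in the RGC list), so a given shift may be detected less often in them. Family ratios are log2((CPM + 0.5)/(CPM + 0.5)) within a library, and a ratio was taken as larger than the spread where its mean exceeded 2 SD with 1 sign in all libraries.

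Genes were named by a rule set before the data were examined. It takes all members of the RGC list, the 4 highest members of every list and the members of cell-class lists above 10 CPM (at most 8). It adds both genes of each pair, the 15 highest genes outside the ribosomal and mitochondrial classes, the 3 highest of those classes, the 10 with the largest SD of log2(CPM + 1) at 50 CPM or more, and list members with an SD over 1. Other members are named as examples of calls below 10 CPM, chosen after their values were seen. XIST and Y-linked genes were left out, and some genes that the rule takes are not reported here. Alternatives covered the normalization (no TMM, DESeq2 1.42.0 size factors), the tool (DESeq2 Wald test, limma 3.58.1 voom), the low-count filter, reference levels of 1, 5 and 20 CPM, pseudocounts, means for medians, length scaling, the RGC list without POU4F2 and THY1, and each replicate left out. Analyses used R 4.3.3 and Python 3.11.15 with scipy 1.17.1 and statsmodels 0.14.6.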

Results

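RNA was sequenced from retinal ganglion cells (RGCs), the projection neurons of the retina, made from the human induced pluripotent stem cell (iPSC) line 201B7. The line carried a reporter at POU4F2, a transcription factor gene of RGCs, which links EGFP and the mouse surface antigen Thy1.2 to the POU4F2 reading frame. Cells were differentiated with small molecules, kept in 25 µM forskolin (an activator of adenylyl cyclase) from day 30, and harvested at day 40. Cells bearing Thy1.2 were captured on magnetic beads, at 100000 cells per sample. The design held 1 group of 3 biological replicates and no other condition, so the comparisons below are between genes and gene lists within these libraries, and between replicates. No unpurified or undifferentiated sample was analysed here, so no value is an enrichment over a starting population. Total counts were 10899049, 4456597 and 6023896 in replicates 1, 2 and 3. Levels are TMM-scaled CPM, counts scaled to the library total times its TMM factor, as mean ± SD with n = 3 throughout.

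The first comparison asked which genes stood clearly above or below a fixed level of 10 CPM, which equals 103, 45.0 and 63.3 counts in the 3 libraries. Outside the ribosomal protein genes, the transcripts at the top of the range were the nuclear non-coding RNA MALAT1 (62648 ± 12723 CPM) and SOX4 (13149 ± 2423 CPM), a transcription factor of newly formed neurons. They were followed by the proteasome subunit gene PSMA7 (10053 ± 2512), the neuronal alpha-tubulin gene TUBA1A (9638 ± 2761), the actin-binding thymosins TMSB10 (7791 ± 637) and TMSB4X (5309 ± 929), the histone genes H3-3B (6782 ± 1048) and H4C3 (2981 ± 1042), and the ferritin light chain gene FTL (6275 ± 1165). The glycolytic genes GAPDH (3905 ± 1272) and TPI1 (3208 ± 722), the retinoic acid binding protein gene CRABP1 (3684 ± 1185), MIF (2973 ± 132) and the actin gene ACTG1 (2945 ± 263) completed the 15 highest of these together with ENSG00000251357 (2971 ± 132 CPM). The last of these overlaps MIF on the same strand and took nearly the same counts in each library, so reads there were counted for both genes. The highest ribosomal protein genes, RPS19 (4163 ± 878), RPS27 (3489.8 ± 330.4) and RPS14 (2999 ± 254), stood above several of these. Of 21336 genes with at least 10 counts over the libraries, 8108 lay above 10 CPM and 10701 below it by edgeR's quasi-likelihood test at an adjusted p under 0.05. Among the 14454 tested protein-coding genes, 7454 lay above.

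Genes of the RGC class were broadly present. Of the 22 members of the RGC list, 17 lay above 10 CPM, 2 below, 2 were not separated from it and 1, POU4F3, had a single count in all. The growth cone gene GAP43 (2591 ± 686 CPM) and the neurofilament light chain gene NEFL (606 ± 95.5 CPM) stood highest. The transcription factor genes ISL1 (168 ± 49.5 CPM), KLF7 (130.3 ± 29.2 CPM), POU4F2 (125 ± 19.6 CPM), EBF1 (97.1 ± 18.3 CPM) and EBF3 (25.7 ± 1.17 CPM) were all above, as was ATOH7 (58.1 ± 15.8 CPM), the factor that makes retinal progenitors competent to form RGCs. The effector genes above 10 CPM were SNCG (128 ± 18.3 CPM), NEFM (92.8 ± 12.3 CPM), the peripherin gene PRPH (83.2 ± 24.3), the nicotinic receptor subunit gene CHRNB3 (42.9 ± 2.87), the vesicular glutamate transporter gene SLC17A6 (38.5 ± 9.80), THY1 (37.4 ± 14.02) and the RNA-binding protein genes RBPMS2 (21.3 ± 3.87) and RBPMS (15.8 ± 1.58). RBPMS had the weakest of these calls (edgeR adjusted p = 0.00242). NEFH (7.62 ± 2.44 CPM, edgeR adjusted p = 0.122) and NRN1 (7.44 ± 2.45 CPM, edgeR adjusted p = 0.0988) were not separated from 10 CPM, and POU4F1 (1.98 ± 0.290 CPM) and CHRNA6 (1.34 ± 0.626 CPM) lay below it. In GRCh38 coordinates of the deposited table, POU4F2 (ENSG00000151615) spans chromosome 4, 146638893 to 146642474, ISL1 (ENSG00000016082) chromosome 5, 51383448 to 51394730, ATOH7 (ENSG00000179774) chromosome 10, 68230595 to 68232113 and POU4F1 (ENSG00000152192) chromosome 13, 78598362 to 78603552. Counts were summed over the exons of each gene. Adjusted over the list alone the calls were again 17 above and 2 below, and the same 17 genes were called with any 1 of the 3 libraries left out. At POU4F2 the reporter cassette lies in the counted locus, and the transcript it makes is not told apart here from the unedited one. Capture through Thy1.2 also selected cells that use this locus, so the POU4F2 level was favoured by the design.

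**Figure D1:**
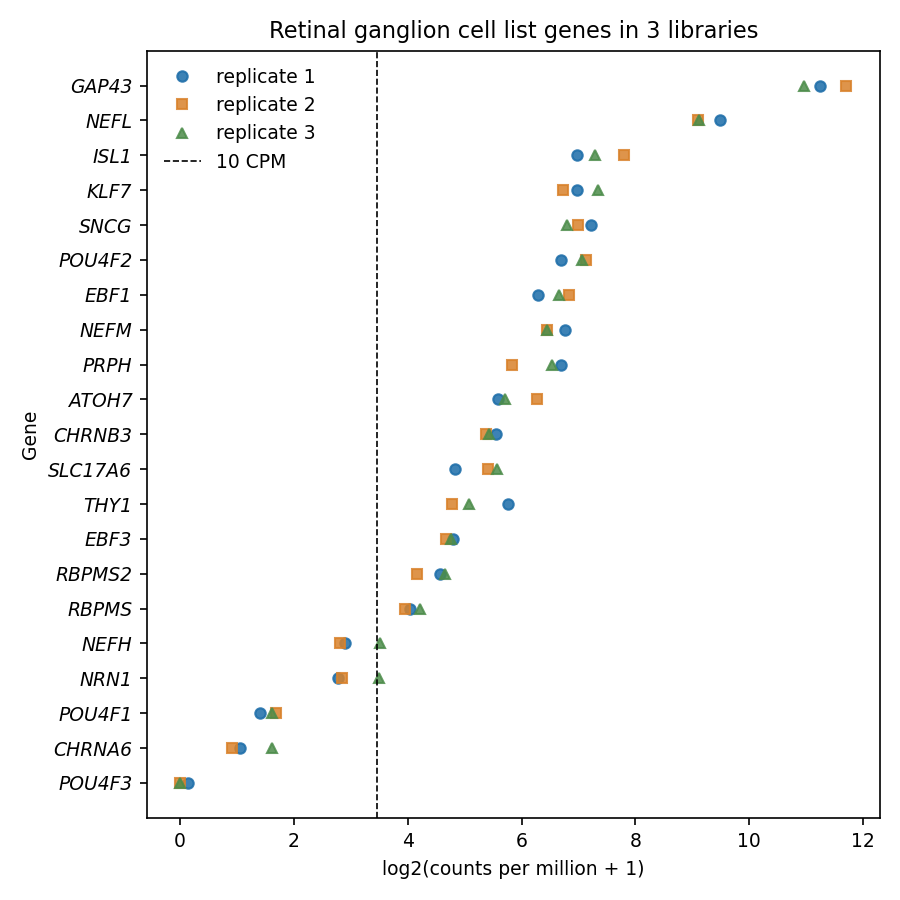
Level of 21 of the RGC list genes in the 3 libraries, as log2(CPM + 1) on the horizontal axis, with 1 symbol per replicate. The dashed line marks 10 CPM. GAP43 and NEFL sit farthest to its right, and POU4F1, CHRNA6 and POU4F3 sit far to its left.

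General neuronal genes were present throughout. All 18 members of the pan-neuronal list lay above 10 CPM, also with each library left out in turn. After SOX4, the highest were the microtubule regulators STMN2 (1689 ± 38.2 CPM) and MAP1B (1331 ± 289 CPM) and the transcription factor gene SOX11 (1128 ± 202 CPM). The lowest member was the synaptic vesicle gene SYP (37.5 ± 15.9 CPM). The beta-tubulin gene TUBB3 (361 ± 37.8 CPM) shares exons with a longer same-strand gene that took nearly the same counts, so its reads were counted for both.

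The second comparison set the RGC list against lists of the other cell classes that the culture or the bead fraction could hold. The median member of the RGC list exceeded that of each of the 11 other lists in 3 of 3 libraries. Lists of photoreceptor, bipolar, pigment epithelium, pluripotency, mesenchymal, sensory and neural crest neuron, and other brain region genes stood 3.80 to 5.52 log2 units lower. On the scale of median log2(CPM + 1), the difference was 4.70 ± 0.27 for photoreceptor genes, 4.52 ± 0.39 for bipolar genes, 3.80 ± 0.39 for pigment epithelium genes and 5.24 ± 0.23 for pluripotency genes. It was 4.55 ± 0.50 for mesenchymal genes, 5.51 ± 0.16 for sensory and crest neuron genes and 5.52 ± 0.11 for genes of other brain regions. Smaller differences separated it from amacrine and horizontal genes (3.50 ± 0.34) and proliferation genes (2.69 ± 0.26). These 9 differences passed a two-sided permutation test of list membership with 100000 resamples, with Benjamini-Hochberg adjusted p from 0.00044 to 0.0078 over the 11 contrasts. The differences from the retinal progenitor list (1.57 ± 0.26, permutation p = 0.13, adjusted p = 0.13) and from the Müller and astroglia list (2.51 ± 0.13, permutation p = 0.11, adjusted p = 0.13) did not pass. With members under 10 counts left out, the Müller and astroglia difference was 0.63 and the pluripotency difference 3.06 (permutation adjusted p = 0.041), and the progenitor difference was 0.52 between list means and 0.56 with counts divided by gene length. With a pseudocount of 0.1 CPM the differences from sensory and crest neuron genes and from other brain regions were 8.34 and 8.29. The permutations run over genes, which are not independent replicates. The pan-neuronal list was not among the 11 contrasts, and its median member stood at 327 CPM against 49.6 CPM in the RGC list. These contrasts therefore do not separate RGCs from neurons in general. An exact sign-flip test over 3 libraries cannot go below p = 0.25. Capture through Thy1.2, linked to POU4F2, favoured a high RGC list beforehand, so these contrasts are not independent of the design.

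**Figure D2:**
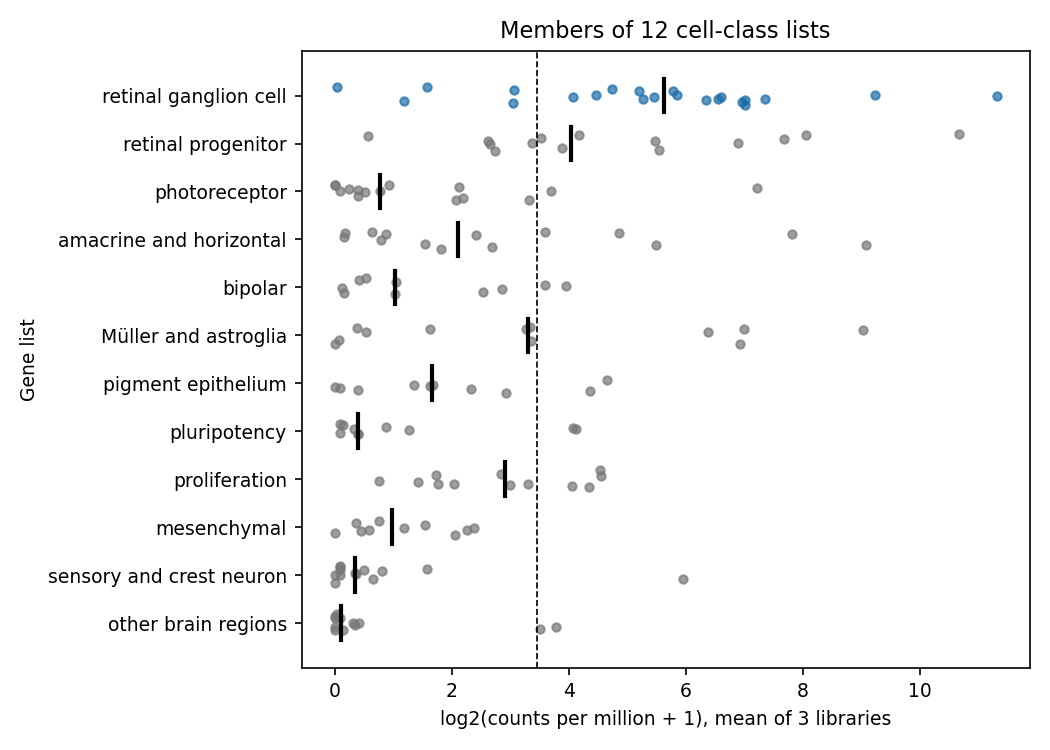
Members of the 12 cell-class lists, each point 1 gene at its mean log2(CPM + 1) over 3 libraries, with vertical jitter for legibility only. Black bars mark list medians and the dashed line 10 CPM. The RGC median lies to the right of all others, and the retinal progenitor median is nearest to it.

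Of the other cell-class lists, the retinal progenitor list had the most members above 10 CPM, at 8 of 14. All 14 were tested. Their share is close to the 51.6% of all tested protein-coding genes above 10 CPM, and was not tested against it. The eye field factor PAX6, which is also kept in RGCs and amacrine cells, stood at 1649 ± 349 CPM, followed by SIX3 (265 ± 22.6 CPM), SIX6 (206 ± 39.6 CPM), RAX (118 ± 14.96 CPM), SOX2 (45.8 ± 2.13 CPM), SFRP2 (43.9 ± 7.18 CPM), HES1 (17.5 ± 4.61 CPM) and LHX2 (13.9 ± 2.80 CPM). LHX2 was no longer called without replicate 3. Of the other members 4 lay below, among them FZD5 (5.19 ± 0.598 CPM) and NR2E1 (0.520 ± 0.380 CPM). Of the 12 proliferation genes, UBE2C (25.2 ± 14.999 CPM), TOP2A (23.5 ± 10.3 CPM), PCNA (19.4 ± 2.02 CPM) and TYMS (15.7 ± 2.64 CPM) lay above and 6 lay below, among them CDK1 (2.41 ± 0.240 CPM) and RRM2 (0.720 ± 0.361 CPM). MKI67, at 7.24 ± 2.90 CPM, was not separated.

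The remaining retinal lists were carried by few members. In the amacrine and horizontal list, 4 of 14 lay above, namely the transcription factor genes ONECUT2 (548 ± 109.9 CPM), ONECUT1 (225 ± 26.8 CPM), PROX1 (44.4 ± 10.7 CPM) and MEIS2 (28.2 ± 5.32 CPM). The inhibitory transmitter genes of that list were lower. GAD1 stood at 11.5 ± 3.77 CPM, not separated from 10 CPM, and SLC32A1 (1.92 ± 0.281 CPM) and GAD2 (0.742 ± 0.306 CPM) lay below. In the photoreceptor list, NEUROD1 (149.97 ± 34.2 CPM) was the 1 member of 15 above. OTX2 (12.7 ± 5.68 CPM) and NRL (9.05 ± 0.673 CPM) were not separated, 5 members including PRDM1 (4.38 ± 4.04 CPM) and CRX (3.55 ± 1.93 CPM) lay below, and 7 had fewer than 10 counts. Without replicate 2, OTX2 passed as well, so that 2 members lay above. In the bipolar list, TMEM215 (14.6 ± 2.72 CPM) was the single member of 10 above, and none was called without replicate 2 or without replicate 3. PRKCA (11.5 ± 3.85 CPM) was not separated, and CA10 (6.41 ± 2.03 CPM) and VSX1 (4.91 ± 1.49 CPM) lay below. In the Müller and astroglia list, 4 of 12 lay above, the secreted chaperone gene CLU (519.6 ± 61.8 CPM), VIM (132 ± 47.2 CPM), DKK3 (121 ± 8.79 CPM) and GLUL (83.7 ± 20.5 CPM). Of the other members, 3 were not separated from 10 CPM, 1 lay below and 4 had fewer than 10 counts, among them RLBP1 with 0 counts in all 3 libraries. A count of 0 allows up to 0.292, 0.666 and 0.474 CPM in replicates 1, 2 and 3, for counting error only. In the pigment epithelium list, PMEL (24.1 ± 0.977 CPM) and SERPINF1 (19.9 ± 4.24 CPM) lay above, while DCT (8.01 ± 6.03 CPM) was not separated and BEST1 (4.19 ± 1.45 CPM) lay below.

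Most members of the lists for cells outside the retina lay below 10 CPM or had fewer than 10 counts, and a few lay above. The core pluripotency genes POU5F1 (0.266 ± 0.156 CPM) and NANOG (0.444 ± 0.769 CPM) had fewer than 10 counts over the libraries, and 2 of 10 members of that list, SALL4 (16.5 ± 2.67 CPM) and DNMT3B (15.7 ± 0.869 CPM), lay above 10 CPM. PODXL (1.47 ± 0.582 CPM) and LIN28A (0.925 ± 0.680 CPM) lay below. Of the 10 mesenchymal genes, 7 lay below and 3 had fewer than 10 counts, and PDGFRB (4.41 ± 1.84 CPM), ACTA2 (3.88 ± 1.05 CPM), TAGLN (3.25 ± 1.23 CPM) and COL1A2 (2.16 ± 1.60 CPM) were the highest. Of the 13 sensory and neural crest neuron genes, 1 lay above, 3 lay below, among them TRPV1 (2.01 ± 0.356 CPM) and RUNX1 (0.618 ± 0.477 CPM), and 9 had fewer than 10 counts. Of the 12 genes of other brain regions, 10 had fewer than 10 counts. The other 2 were not separated, among them TH (13.1 ± 3.90 CPM, edgeR adjusted p = 0.065), which was called above without replicate 2 or without replicate 3, and the next were EN2 (0.360 ± 0.287 CPM) and HOXB2 (0.329 ± 0.487 CPM). In a list of blood, vessel, epithelial and lens genes, CRYAB was the 1 member of 16 above, at 46.2, 11.5 and 8.21 CPM in replicates 1, 2 and 3, and it was not called without replicate 1. CRYAA (8.98 ± 4.52 CPM) was not separated, and EPCAM (3.79 ± 2.06 CPM) and KRT18 (2.25 ± 1.32 CPM) lay below.

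Lists of neuronal function were counted in the same way, beside 51.6% of all tested protein-coding genes above 10 CPM, and no list's share was tested against that share. The 51.6% leaves out genes with fewer than 10 counts, whereas the list counts keep such members (8 of 18 in the RGC subtype list), so the bases differ. In the RGC subtype list, 5 of 18 lay above, among them FOXP1 (104 ± 16.0 CPM), SPP1 (64.5 ± 4.68 CPM), SATB1 (23.3 ± 5.03 CPM) and FSTL4 (22.4 ± 1.97 CPM). Melanopsin (OPN4), EOMES and TBR1 had fewer than 10 counts over the libraries. Axon guidance genes lay above in 14 of 19 cases, led by the collapsin response mediators DPYSL3 (382 ± 22.2 CPM) and CRMP1 (272 ± 10.6 CPM) and the adhesion genes CNTN2 (128 ± 38.1 CPM) and NRCAM (74.7 ± 7.60 CPM). Synaptic receptor genes lay above in 9 of 16 cases, with the AMPA receptor subunit gene GRIA2 at 280.5 ± 3.74 CPM, the nicotinic subunit gene CHRNA3 at 217 ± 145 CPM and GRIA4 at 41.0 ± 7.68 CPM. The obligatory NMDA receptor subunit gene GRIN1 lay below at 1.15 ± 0.101 CPM. Ion channel genes lay above in 9 of 17 cases, among them CACNA2D1 (90.3 ± 10.8 CPM), SCN2A (55.7 ± 6.18 CPM) and SCN3A (49.7 ± 9.09 CPM). Of the 12 neurotrophic receptor genes, 6 lay above, led by IGF1R (102 ± 43.6 CPM), GFRA2 (36.0 ± 4.41 CPM), GFRA1 (30.4 ± 3.01 CPM) and LIFR (21.99 ± 1.33 CPM).

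Genes that respond to cyclic AMP in many cell types lay above in 8 of 17 cases, which is a level in forskolin-treated cells without an untreated control. EGR1 (134 ± 32.9 CPM), the somatostatin gene SST (92.2 ± 14.9 CPM), DUSP1 (75.7 ± 8.49 CPM) and CREM (52.3 ± 4.14 CPM) were highest. NR4A1 (2.93 ± 0.235 CPM), NR4A2 (0.593 ± 0.469 CPM) and BDNF (2.59 ± 0.472 CPM) lay below. Stress and axon injury genes lay above in 11 of 16 cases, led by the endoplasmic reticulum chaperone gene HSPA5 (626 ± 66.2 CPM), JUN (512 ± 128 CPM), GADD45A (124 ± 1.34 CPM) and DDIT3 (100.3 ± 32.7 CPM). HSPA1A and HSPA1B are near-identical copies whose reads may not be told apart, and the treatment of such reads is not given. Neither gene was separated from 10 CPM. HSPA1B also shares exons on the same strand with ENSG00000285565 (36.1 CPM). Of 16 genes linked to optic nerve disease or axon survival, 10 lay above, led by OPTN (136 ± 19.3 CPM), NMNAT2 (99.6 ± 9.17 CPM) and OPA1 (54.0 ± 15.8 CPM). MYOC, ANGPT1 and TEK had fewer than 10 counts over the libraries. For these lists the numbers above and below were the same when adjusted over the list alone, except that 2 rather than 3 synaptic receptor genes lay below. With any 1 library left out, the synaptic receptor count above fell to 8 and the optic nerve count to 9. The axon guidance count fell to 12 without replicate 3, the neurotrophic receptor count to 5 without replicate 2 or 3, and the stress count to 10 without replicate 1. The RGC subtype count rose to 6 without replicate 2. The ion channel and cyclic AMP counts did not change.

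The third comparison set members of gene families against each other within each library. POU4F2 exceeded POU4F1 by 5.66 ± 0.07 on the log2 scale, with a ratio of mean CPM of 63.3, and ISL1 exceeded ISL2 by 6.74 ± 1.00. POU4F2 had 1055, 629 and 841 counts where POU4F3 had 1, 0 and 0. Capture through Thy1.2, linked to POU4F2, favoured a high POU4F2 level beforehand, so the POU4F ratios are not independent of the design. EBF1 exceeded EBF3 (1.88 ± 0.34), EBF4 (4.15 ± 0.59) and EBF2 (6.72 ± 0.57), the last with 6, 1 and 3 counts, where the ratio depends on the pseudocount (7.58 with 0.1 CPM). The neurofilament light chain gene NEFL exceeded NEFM by 2.697 ± 0.03 and NEFH by 6.25 ± 0.53. SLC17A6 exceeded the other vesicular glutamate transporter genes SLC17A7 (2.90 ± 0.41) and SLC17A8 (4.17 ± 0.62). In ratios of mean CPM, SOX4 was 11.7-fold higher than SOX11, which on the log2 scale exceeded SOX12 by 4.53 ± 0.43. By the same ratio DLX1 was 5.62-fold higher than DLX2, RBPMS2 exceeded RBPMS 1.35-fold and ELAVL3 exceeded ELAVL4 2.99-fold.

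SNCG exceeded SNCB by 4.99 ± 0.67 on the log2 scale. STMN2 exceeded STMN3 (4.65 ± 0.29) and STMN4 (1.07 ± 0.19). STMN1 was 1.203-fold higher than STMN2 by mean CPM, an order that turned when counts were divided by gene length (STMN2 over STMN1 then 1.35 on the log2 scale). SCN3A exceeded SCN1A (2.11 ± 0.40) and SCN8A (1.49 ± 0.26), and NMNAT2 exceeded NMNAT1 (3.13 ± 0.11) and NMNAT3 (4.69 ± 0.40). With counts divided by gene length, pairs whose ratio moved by over 1.5 times and kept its sign included RBPMS over RBPMS2 (-2.37), STMN2 over STMN4 (1.77) and ELAVL4 over ELAVL3 (-2.34). In 5 pairs the difference did not exceed the spread, and these were NTRK2 over NTRK3 (1.86 ± 1.05), GRIN2B over GRIN2A (-0.13 ± 0.44), SCN3A over SCN2A (-0.17 ± 0.11, but 0.83 with counts divided by gene length), SLC12A5 over SLC12A2 (0.42 ± 0.42) and ELAVL4 over ELAVL2 (-0.36 ± 0.24). Of the 30 pairs, 25 had a mean above 2 SD with the same sign in 3 of 3 libraries. The exact sign-flip test gave its smallest two-sided p of 0.25 for the 28 pairs that shared a sign in 3 libraries, so no pair can pass a threshold of 0.05.

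The last comparison was between the replicates. Across the 21336 tested genes, log2(CPM + 1) correlated with a Pearson r of 0.980 between replicates 1 and 3, 0.964 between 1 and 2, and 0.961 between 2 and 3, and genes are not independent replicates. Counts of each pair differed by far more than sampling noise, with a chi-square per degree of freedom of 10.1 to 13.9, so no pair agreed within that noise. Separate preparations of 1 sample would exceed it too, and that the cultures were separate rests on the series' description. The common biological coefficient of variation was 0.249 over all tested genes and 0.187 over the genes with a mean of at least 10 CPM. The 10 genes with the most spread at a mean of 50 CPM or more were, in CPM of replicates 1, 2 and 3, TOX-DT (22.2, 105 and 28.4), AKAP11 (335, 601 and 119.7), TALAM1 (678, 2899.6 and 892), NUDT3 (101, 96.2 and 348), CHRNA3 (136, 384 and 131), LINC00632 (104, 33.1 and 71.2), RBFOX3 (162, 55.3 and 74.8), LRP2 (196, 396 and 137), ACVR2B (454, 904 and 313) and PPP1R11 (117, 42.9 and 71.5). TALAM1, the antisense partner of MALAT1, had 0.877%, 5.21% and 1.62% of the counts of MALAT1 in replicates 1, 2 and 3, and NUDT3 shares exons with a readthrough gene. Of all members of the 22 lists with a mean of at least 10 CPM, CRYAB was the one whose SD of log2(CPM + 1) exceeded 1.

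Replicate 2 had the fewest counts and yet at least 1 count in the most genes, 32809 against 29389 in replicate 1 and 27344 in replicate 3. Thinned to the 4456597 counts of replicate 2, replicates 1 and 3 had a count in 25522 and 26039 genes on average over 10 draws.

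**Figure D3:**
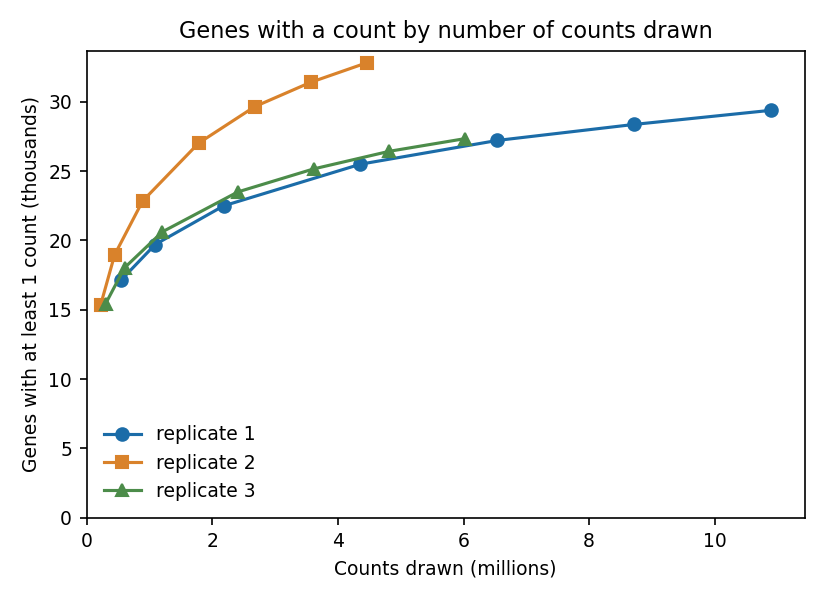
Genes with at least 1 count (vertical axis) against counts drawn at random from each library (horizontal axis), in the units given on the axes, with the last point of each line at the full library. At its full 4456597 counts, replicate 2 lies above both other libraries.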

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

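The list counts with 1 replicate left out were chosen after the data were seen, as was the form of the DESeq2 test. No paired analysis was possible because there is 1 group of samples. Of the 98 alternatives run on the 11 list contrasts, 97 kept the direction and the side of the threshold. In the exception, values scaled by gene length gave 2.99 for the RGC minus Müller and astroglia difference, with a permutation adjusted p of 0.0129 against 0.13 in the main comparison, and the adjusted p over all alternatives of that contrast ran from 0.0129 to 0.495. The cause was not tested. For the list of other brain regions, leaving out members with fewer than 10 counts left too few genes to compare. The number of genes above 10 CPM was 15070 with a reference of 1 CPM, as the lower reference implies. The number below was 27983 without the low-count filter, where more genes are tested, and 0 with a reference of 1 CPM by edgeR, with 0 at an unadjusted p under 0.05 and 0 by limma-voom. The cause of these counts of 0 was not tested. All other settings, DESeq2 and limma-voom included, kept both counts within 1.5 times, and the counts with 1 replicate left out ranged from 7709 to 8118 above and from 7387 to 8506 below. The share of family pairs larger than the spread stayed within 1.5 times, and of 150 alternatives on the 30 pairs 127 moved by less than 1 SD. Of the 22 that moved further, 21 kept their sign and SCN3A over SCN2A, which did not exceed the spread, changed it. The order of STMN2 and STMN1 turned under length scaling (1.35). Length scaling gave 19 of the 22 moves and the lower pseudocount 3. Length scaling fits reads spread along transcripts rather than 3′ ends. The alternative that takes mitochondrially encoded genes out of the totals was not run, because it would change no value. A first form of the DESeq2 Wald test scaled the size factors to the reference level, which broke its dispersion fit and called no gene below. The form used, with centred size factors and the reference subtracted from the intercept, replaced it after that output was seen and called 7915 genes above and 10160 below. The lowest depth, 4456597 counts in replicate 2, puts a gene at 10 CPM at 45.0 counts, so levels near or under 1 CPM rest on a few counts.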

Other observations

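Tests of the ONECUT genes and of a general shift in replicate 3 were chosen after the results were seen. The enrichment test was also added after the data were seen. The other tests were set before their values were known, but the readings of the ONECUT, repeat-copy, opposite-strand and general-shift tests were revised after their values were seen. Beyond the fixed lists, gene ontology terms given in the deposited table were tested for enrichment among the 1670 annotated genes with a mean of at least 100 CPM, against 13870 tested and annotated genes. Of 3410 terms, 185 passed (one-sided hypergeometric test, Benjamini-Hochberg). Protein synthesis led, with 84 of 89 genes of cytoplasmic translation against 10.7 expected by chance (adjusted p = 7.08e-68). Mitochondrial energy supply followed, with 43 of 54 genes of ATP synthesis driven by the proton gradient against 6.50 expected (adjusted p = 2.21e-27), and 33 of 41 genes of respiratory chain complex I against 4.94 expected (adjusted p = 5.32e-21). Splicing genes (65 of 180, 21.7 expected, adjusted p = 9.53e-15) and proteasome genes (27 of 53, 6.38 expected, adjusted p = 7.36e-10) were also over-represented. Terms share genes and genes are not independent. These are features of the most abundant transcripts, and with no other cell type compared, whether they are particular to RGCs cannot be told. H4C3, a histone gene of the class used in DNA replication, stood among the 15 highest genes at 2981 ± 1042 CPM, while the proliferation list had a median member at 6.72 CPM.

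ONECUT1 and ONECUT2, listed here with amacrine and horizontal cells, stood at 225 ± 26.8 and 548 ± 109.9 CPM. If amacrine or horizontal cells in the purified fraction were their source, the factors PTF1A, TFAP2A, TFAP2B and LHX1 should reach at least 0.1 of the ONECUT1 level. Their median ratio to ONECUT1 was at most 0.00437 in any library, but these genes lay near the floor, the bound of 0.1 is an assumption, and other members of the list exceeded it (PROX1 at 0.198 and MEIS2 at 0.126 of ONECUT1). Those cells therefore stay open as a source. Expression of both genes in the RGCs or their precursors may also account for the levels, and bulk libraries cannot tell these apart.

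Replicate 2 had counts in the most genes with 0.74 times the total counts of the next library. Thinned to an equal 4456597 counts, replicates 1 and 3 had a count in 25522 and 26039 genes on average, against 32809 in replicate 2. These values argue against the number of counts as the cause of this pattern in these libraries. Reads spread thinly over genes that these cells do not use were tested on 617 genes of families such as olfactory and taste receptors. They summed to 92.8 CPM in replicate 2 (95% exact Poisson interval 84.2 to 102) against 26.2 (23.2 to 29.5) and 25.7 (21.9 to 30.0), a ratio of 3.541, which is consistent with a thin background in that library. Repeat copies of few molecules in replicates 1 and 3 stay open, because their excess of genes at 0 (2.67 percentage points more than in replicate 2) is also what a background in replicate 2 would leave. More reads opposite to expressed genes stay open too, since over 195 non-coding genes the median excess was 0.09 log2 units with a 95% bootstrap interval of -0.000768 to 0.304, and the planned reading of an interval including 0 as exclusion was wrong because most of it lies above 0.

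Of the 12 dividing-cell genes, 9 stood highest in replicate 3, 2 in replicate 2 and 1 in replicate 1, with UBE2C at 12.8, 20.9 and 41.8 CPM and PCNA at 21.5, 19.1 and 17.5 CPM in replicates 1, 2 and 3. The proliferation list's median difference of replicate 3 from the others, 0.30 log2 units, lay at percentile 96.9 among 10000 random lists of matched level and 97.7 among lists matched on level and gene length, which argues against gene length. A general shift cannot be told apart, since these percentiles lie on either side of the bound set for that test and 14 of 21 lists lay above the 90th percentile in replicate 3, the pan-neuronal list included. More dividing progenitors in that culture is a candidate explanation that stays open, with the retinal progenitor list at percentile 93.2 among level-matched lists and 98.0 among lists also matched on length. In replicate 1 the proliferation list's median difference from the others was -0.438 log2 units, at percentile 0.18 among level-matched lists. In replicate 2 it was -0.126, at percentile 28.7. The pan-neuronal list was also low in replicate 1, at percentile 0.06. A high replicate 3 and a low replicate 1 therefore cannot be told apart. Each statement describes 1 library and has no replicate check.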
